A study of Homo sapiens with 7 samples.

How the data were processed

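The study measured the positions of histone marks and of p300 in MCF-7 cells by ChIP-seq. Per the labels' protocols, chromatin for the histone marks was digested with micrococcal nuclease to mononucleosomes after fixation of nuclei with 0.2% formaldehyde, whereas chromatin for p300 was sonicated after fixation of whole cells with 1% formaldehyde. The 2 lists therefore differ in fragment length and fixation as well as in antibody. Processed files of the H3K122ac and the p300 samples were used, and the other 5 of the 7 samples, inputs included, were not analysed here. Each sample is a group of its own with 1 library, so no comparison has biological replicates and no difference was checked against the spread between cultures.

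Each deposited list gives one interval per line, with a chromosome, start and end, a position inside the interval as part of its name, a score and a strand sign that is the same throughout. The intervals use genome build hg18, per the submitters' processing notes, and starts and ends fall on a grid of 10 bp. The names of the deposited lists point to the peak caller CCAT and a false discovery rate of 1%, and no label or file header describes the calling. The aligner, the caller's version and settings and the way the inputs were used are not given in the sources used here. The deposited score is the authors' own value per interval. Both lists are sorted by this score, what it measures is not stated, and it was used only to rank or compare intervals within one list. Intervals of the p300 list are called peaks here and those of the H3K122ac list regions. Both lists repeat some intervals with another position in the name, and the position lay inside its interval throughout. Each list belongs to 1 sample, so no libraries of different samples were pooled as far as the labels say.

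Intervals were analysed as deposited with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Coordinates are printed counting from 1. Overlap meant at least 1 shared bp. The chance level came from 10000 random rotations of the p300 peaks within each chromosome, over the span from the first start to the last end of either list. Rotation keeps the widths and spacing of the peaks. These permutation tests were one-sided for more overlap or shorter distance. A difference of medians between intervals with and without overlap was tested by 100000 two-sided permutations of the labels. The 95% intervals of shares, medians and differences came from 1000 bootstraps of 5 Mb blocks of the genome, and the intervals of shares within deciles, wide regions or chromosomes are Wilson intervals, which cover counting error only. Neighbouring distinct H3K122ac regions at most 12.5 kb apart were stitched, and clusters had at least 3 regions. Chromosome shares were compared through the bootstrap interval of their difference.

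The comparisons, the alternatives listed first and the rule for named regions were fixed before the data were examined. The rule named the 5 widest H3K122ac regions with and without p300, the 5 clusters with most covered sequence, the 5 highest-scoring p300 peaks inside and outside H3K122ac regions, and the 3 chromosomes with the largest difference of shares in each direction. A repeated interval was named once, with its highest score. Chromosomes 13, 18, 19 and X and the wide-region counts fall outside the rule and were chosen after their values were seen. The shares by decile and the counts among the 100 highest-scoring intervals were added to the fixed comparisons. Alternatives required 50% of the p300 peak, or its centre, to lie in the region, allowed 1 kb of distance, kept the 50% of each list with the highest scores, shifted each peak on its own by up to 1 Mb or 50 kb, merged overlapping intervals, left out the chromosome with most p300 peaks, or stitched at 5000 or 25000 bp. Added after seeing the data were the position in the name in place of the interval, merging for counts of intervals and for chromosome shares, the rotated p300 peaks as a second chance level for width and score, the removal of the 2 densest p300 windows of 5 Mb, and draws of regions in proportion to their width plus the mean p300 width and to the p300 peaks per Mb of their chromosome. Tests of promoters and of gene lists had been planned for the case that an hg18 annotation was at hand. None was used here, since the gene table at hand follows another build, and regions are therefore given by position without gene names.

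The overlap test was checked on simulated p300 peaks with the real widths. Peaks not placed on a region were each moved at random on their own, so the test was not checked under the real crowding. The recovered share is corrected for the mean overlap of rotated peaks, unlike the shares given in the results. When 50% of the 2165 peaks were placed on H3K122ac regions, the recovered share was 50.0% ± 0.189 (SD over 10 simulated sets), and with 5% placed it was 4.99% ± 0.261 (SD over 10 simulated sets). With none placed, 4 of 40 simulated sets passed a threshold of 0.05, where 5% of sets would pass on average. The files give no read counts, so no depth and no interval that needs it can be stated.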

Results

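Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in MCF-7, an estrogen receptor-positive human breast cancer cell line. The cells had been kept for 3 days without phenol red in medium with 5% charcoal-stripped serum, which removes steroid hormones. The series holds 7 samples with 1 library each: ChIP of histone H3 carrying K122 acetylation (H3K122ac), of H3K27ac, of the histone variant H2A.Z, of acetylated H2A.Z and of the acetyltransferase p300, and an input for each of the 2 chromatin preparations. Lists of enriched intervals were used for H3K122ac and p300, and the other 5 samples were not analysed here. H3K122 lies on the lateral surface of the histone octamer, where the histones contact DNA. The series title names transcriptional regulation through this acetylation as its subject. Both lists use hg18 coordinates and come from single libraries, so the intervals given here cover the spread along the genome or counting error and not the spread between cultures. The lists carry no read counts, and the sequencing depth behind each interval is unknown.

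H3K122ac was enriched at 17682 regions on 23 chromosomes, and p300 at 2165 peaks on the same chromosomes. The H3K122ac regions had a median width of 1210 bp, with an interquartile range of 850 to 1680 bp. They covered 24.04 Mb in all. The p300 peaks had a median width of 910 bp, with an interquartile range of 720 to 1310 bp, and covered 2.27 Mb. The median gap between neighbouring intervals was 52.6 kb for H3K122ac and 322 kb for p300. In the p300 list 87 peaks repeated the interval of another peak with a different position in its name, and in the H3K122ac list 22 regions did, which leaves 2078 and 17660 distinct intervals. Among the H3K122ac regions the authors' score ran from 8.54 to 58.2, and among the p300 peaks their score ran from 9.73 to 144. The scores served only to rank and compare intervals within their own list.

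The first comparison asked whether p300 occupied the places that carry H3K122ac. Of the 2165 p300 peaks, 1119 overlapped an H3K122ac region by at least 1 bp. This was 51.7% of the peaks, with a 95% block-bootstrap interval of 48.2 to 55.1%. When the p300 peaks were rotated at random within their chromosomes, 1.88% overlapped a region on average, with a central 95% range of 1.20 to 2.77%. The observed share was 27.5 times that mean and was above every one of the 10000 rotations (one-sided permutation test, p = 0.0001, the smallest these rotations can give). Rotation can place peaks in stretches where neither list has intervals, which lowers the chance level. No other mark was compared, so the excess is not shown to be particular to H3K122ac. Chance overlap rose when peaks were moved only within their neighbourhood. Shifts of up to 1 Mb gave 3.75% and shifts of up to 50 kb gave 7.58%, and the observed share remained 6.82 times the latter (permutation test, p = 0.0001).

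In the other direction the share is limited by the length of the lists, since there were 2165 p300 peaks for 17682 regions. Of the 17682 H3K122ac regions, 1083 held a p300 peak, which was 6.12% (95% block-bootstrap interval 5.48 to 6.79%). Rotated p300 peaks met 0.211% of the regions on average (one-sided permutation test, p = 0.0001). The remaining 16599 H3K122ac regions held no p300 peak at the authors' threshold. Most of the overlapping p300 peaks met a single region (1045 peaks), and 74 met 2 or more. Counted as listed, repeated intervals included, up to 7 p300 peaks fell in one H3K122ac region.

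**Figure D1:**
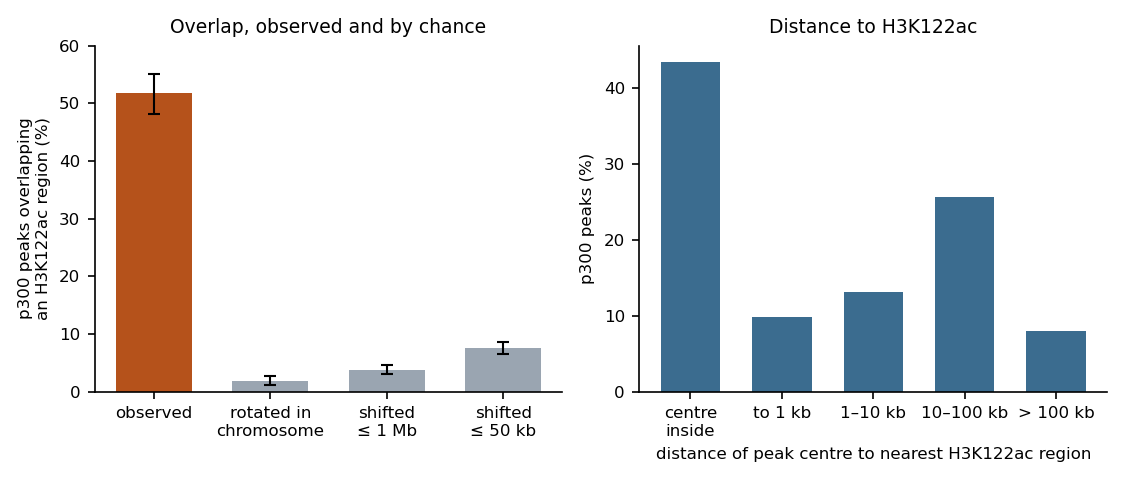
Left, percent of p300 peaks that overlap an H3K122ac region: the observed bar has a 95% block-bootstrap interval, and the other bars are means with central 95% ranges of p300 peaks rotated within the chromosome or shifted by up to 1 Mb or 50 kb. Right, percent of p300 peaks in each class of distance from the peak centre to the nearest H3K122ac region. The observed 51.7% lies above the 1.88, 3.75 and 7.58% of the displaced peaks, and 43.4% of the peak centres lie inside a region.

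The centre of the p300 peak lay inside an H3K122ac region for 940 peaks (43.4%), and within 1 kb of one for a further 213 peaks (9.84%). Another 283 peaks (13.1%) lay 1 to 10 kb away, 555 (25.6%) lay 10 to 100 kb away, and 174 (8.04%) lay farther. The median distance over all peaks was 335 bp, with a 95% block-bootstrap interval of 81.0 to 1130 bp. It was 84391 bp for rotated peaks and 36508 bp for peaks shifted by up to 1 Mb (one-sided permutation tests, p = 0.0001 for each). The observed median was 546 bp without the 2 windows of 5 Mb that held most p300 peaks, which lies inside that bootstrap interval. It was 16071 bp when both lists were restricted to the 50% of intervals with the highest scores, which leaves 8841 regions. Rotated peaks gave 160986 bp in that setting.

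Overlap was more frequent among p300 peaks of high score. In the highest decile of p300 score, 149 of 216 overlapped an H3K122ac region (69.0%, 95% Wilson interval 62.5 to 74.8%). In the lowest decile 93 of 217 did (42.9%, interval 36.5 to 49.5%). Peaks of high score were also wider, with a median of 1150 bp in the highest and 790 bp in the lowest decile, and a wide peak meets a region more easily. The overlap by score was not tested at matched width. The median score was 12.9 for the 1119 peaks inside regions and 12.1 for the 1046 peaks outside, and their median widths were 1050 and 790 bp. The difference of medians was 0.807 (95% block-bootstrap interval 0.679 to 1.35; two-sided permutation test, p = 0.00301). Against rotated p300 peaks the same difference did not pass 0.05 (two-sided permutation p = 0.28).

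The highest-scoring p300 peak inside an H3K122ac region lay on chromosome 1 at 179370501-179371340, with a score of 102. The next ones were at chromosome 20, 52256971-52259780 (score 83.5), chromosome 9, 125069531-125071430 (72.6), chromosome 17, 56839951-56845710 (72.2), and chromosome 3, 171422281-171423740 (63.7). The highest score of the whole p300 list belonged to a peak without H3K122ac. It lay on chromosome 17 at 28173181-28174360, scored 144, and was 54.6 kb from the nearest region. The other leading peaks outside regions were at chromosome 11, 63809281-63810390 (score 87.9, at 13.7 kb), chromosome 1, 154452491-154453640 (80.2, at 2.51 kb), chromosome 17, 68147921-68149090 (67.8, at 47.7 kb), and chromosome 9, 136443721-136444650 (58.9, at 453 kb). No hg18 gene annotation was used, so these positions are given without genes. Among the 100 highest-scoring p300 peaks, 71 overlapped an H3K122ac region, against 51.7% of all p300 peaks. For the 100 highest-scoring H3K122ac regions, 19 overlapped a p300 peak, against 6.12% of all regions. The 2 counts cannot be set against each other, since the lists differ in length.

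H3K122ac regions that held p300 were wider than those that did not. Their median width was 1660 bp (n = 1083) against 1180 bp (n = 16599). The difference was 480 bp, with a 95% block-bootstrap interval of 370 to 550 bp (two-sided permutation test over regions, p = 1e-05, the smallest these permutations can give). Regions are not biological replicates, and this p describes the 2 lists only. Wide regions offer more room for a peak, so 1083 regions were also drawn in proportion to their width and to the p300 density of their chromosome. The difference was then 187 bp on average, with a central 95% range of 130 to 240 bp (two-sided permutation p = 0.0002). These draws picked regions independently of each other and did not keep the crowding of p300 peaks, so this range may be too narrow. The observed 480 bp did not pass 0.05 against rotated p300 peaks, which met 37.3 regions on average and gave a central 95% range of -110 to 530 bp (two-sided permutation p = 0.0916). Regions with 1 p300 peak had a median width of 1620 bp (n = 1003), and those with 2 or more had a median of 2925 bp (n = 80), a difference that was not tested. Peaks were counted as listed, so a region with 1 p300 interval listed several times falls in the second class. The difference therefore does not separate several p300 sites from 1 interval with several positions. In the widest decile of H3K122ac regions, 301 of 1768 held p300 (17.02%, Wilson interval 15.3 to 18.8%). In the narrowest decile 43 of 1769 did (2.43%, interval 1.81 to 3.26%).

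The authors' score of H3K122ac regions was also higher where p300 was present. The medians were 14.4 with p300 and 12.2 without, a difference of 2.14 (95% block-bootstrap interval 1.32 to 2.87; two-sided permutation test, p = 1e-05). This difference did not pass 0.05 against rotated p300 peaks either (two-sided permutation p = 0.294). Score and width were related across H3K122ac regions (Spearman's rho = 0.46 across regions, which are not independent replicates). Within deciles of width the score difference was 0.513 (two-sided permutation test, p = 0.00519).

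**Figure D2:**
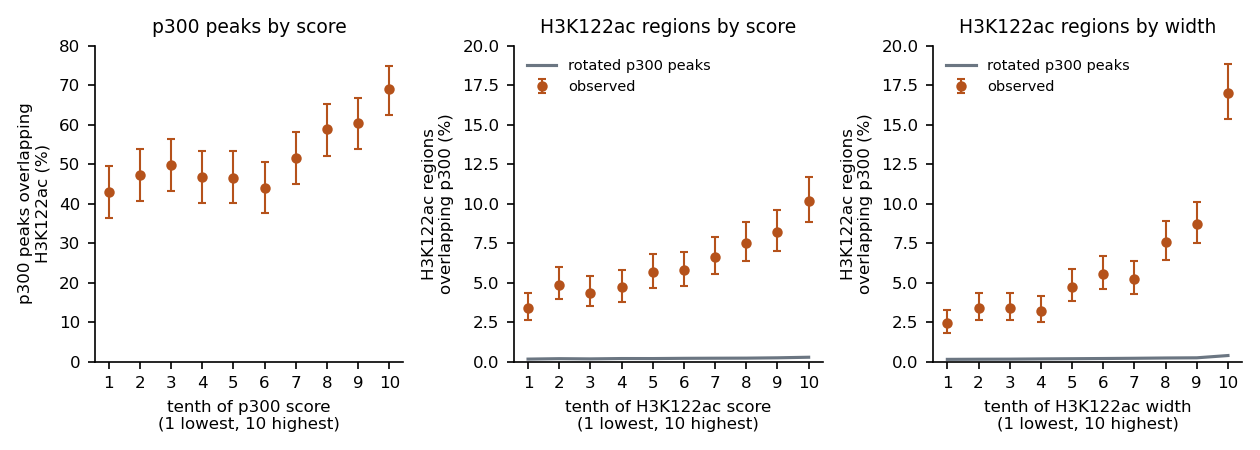
Percent of intervals that overlap the other list, in deciles of the p300 score (left), the H3K122ac score (middle) and the H3K122ac width (right). Points are observed percentages with 95% Wilson intervals (counting error only), and grey lines, in the middle and right plots, are the means of 10000 rotations of the p300 peaks. The share of p300 peaks runs from 42.9% in the lowest to 69.0% in the highest decile of score, and the share of H3K122ac regions from 2.43% in the narrowest to 17.02% in the widest decile.

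The widest H3K122ac regions were concentrated on chromosome 20. Of the 15 distinct regions at least 10 kb wide, 12 lay on chromosome 20, 2 on chromosome 17 and 1 on chromosome 21, although chromosome 20 held 4.18% of all H3K122ac regions. The widest of all was a region of 19.5 kb on chromosome 17 at 55274191-55293640, and it held 6 p300 peaks. The next with p300 were on chromosome 20 at 51700381-51717090 (16.7 kb, 2 p300 peaks), 45412591-45428330 (15.7 kb, 6 peaks), 48831861-48847160 (15.3 kb, 4 peaks) and 45376131-45388250 (12.1 kb, 2 peaks). These p300 peaks were counted as listed, so 1 interval listed with several positions counts several times. Comparable widths occurred without p300. On chromosome 20 these were 51733681-51748920 (15.2 kb), 51834141-51848400 (14.3 kb), 48759271-48769610 (10.3 kb) and 51849531-51859760 (10.2 kb), and on chromosome 21 a region of 11.3 kb lay at 40626551-40637820. Among the 71 distinct regions of at least 5 kb, 39 lay on chromosome 20 and 32 held p300 (45.1%, Wilson interval 34.05 to 56.6%). Long arms of chromosomes 17 and 20 are known to carry amplified segments in MCF-7.

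Neighbouring H3K122ac regions formed clusters, some of which also carried several p300 peaks. Stitching regions at most 12.5 kb apart gave 666 clusters of 3 or more distinct regions, which together contained 2517 regions. Of these clusters, 161 held a p300 peak (24.2%, 95% block-bootstrap interval 19.9 to 28.3%). Rotated peaks fell in 1.79% of the clusters on average (one-sided permutation test, p = 0.0001), and peaks shifted by up to 1 Mb fell in 5.77%. Clusters consist of regions that already met p300 more often than rotated peaks did. The test therefore cannot show an excess particular to clusters. The clusters contained 274 p300 peaks, which was 12.7% of that list, and 14.2% of the H3K122ac regions. Among the clusters, 23 held 3 or more p300 peaks. The cluster with most H3K122ac-covered sequence spanned 189 kb on chromosome 20 at 51691331-51880580, with 19 regions, 117 kb covered and 5 p300 peaks. A cluster on the same chromosome at 45374611-45459890 spanned 85.3 kb with 12 regions and 13 p300 peaks. On chromosome 6 a cluster at 152010351-152070140 had 14 regions over 59.8 kb and 1 p300 peak. The fourth cluster lay on chromosome 20 at 48396151-48519150, with 21 regions and 3 p300 peaks, and the fifth on chromosome 17 at 55261391-55293640, with 3 regions and 8 p300 peaks. The p300 peaks in clusters were counted as listed, so repeated intervals counted several times, whereas regions were counted as distinct.

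**Figure D3:**
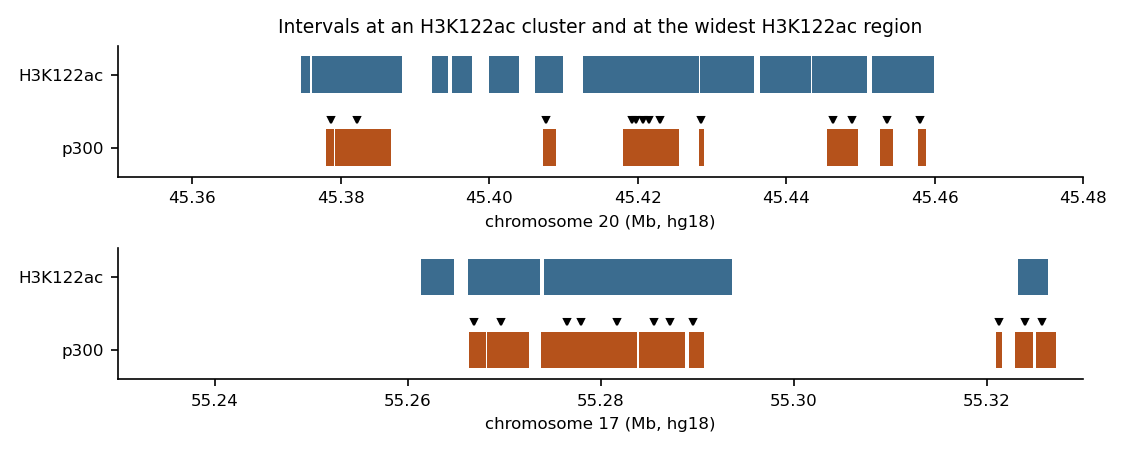
Intervals of the 2 lists, to scale in hg18 coordinates, at the chromosome 20 cluster that starts at 45374611 (top) and around the widest H3K122ac region, on chromosome 17 at 55274191-55293640 (bottom). Blue boxes are H3K122ac regions, orange boxes are p300 intervals and black triangles are the positions given in the p300 interval names. The chromosome 20 cluster holds 12 H3K122ac regions and 13 p300 peaks, and the widest region holds 6 p300 peaks. Peaks are counted as listed, and repeated p300 intervals are drawn on top of each other.

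The 2 lists were spread differently over the chromosomes. Chromosomes 17, 20 and 7 held a larger share of the p300 peaks than of the H3K122ac regions. Chromosome 17 held 8.91% of the p300 peaks and 4.83% of the H3K122ac regions, a difference of 4.08 percentage points (95% block-bootstrap interval 0.176 to 9.26). Without the 2 densest p300 windows of 5 Mb, this difference was 1.83 points and its interval included 0 (-0.127 to 4.27). On chromosome 20 the shares were 7.62% and 4.18% (difference 3.44 points, interval 0.514 to 6.80), and the difference was 1.91 points without those windows and 2.13 points among the 50% of intervals with the highest scores. On chromosome 7 they were 7.62% and 4.76% (difference 2.87 points, interval 0.688 to 5.21). The p300 share was lower than the H3K122ac share on chromosome 4 (1.15% against 3.55%, interval of the difference -3.05 to -1.74), on chromosome 10 (2.63% against 4.87%, interval -3.02 to -1.45) and on chromosome 2 (5.59% against 7.75%, interval -3.44 to -0.877). For chromosome 2 the interval included 0 among the 50% of intervals with the highest scores (-3.94 to 0.402). In all, the interval excluded 0 on 12 of 23 chromosomes, 3 with a larger and 9 with a smaller p300 share. About 1.15 would be expected by chance if each interval had exactly its stated 95% coverage, which was not checked. The differences sum to 0, so an excess on some chromosomes forces a deficit on others, and the 12 are not separate results. Merging overlapping intervals left 10 such chromosomes, and leaving out the 2 densest windows left 9. Restricting both lists to the 50% of intervals with the highest scores left 7, 3 with a larger and 4 with a smaller p300 share. H3K122ac regions were densest on chromosome 20, with 11.9 per Mb, and sparsest on chromosome X, with 2.60 per Mb.

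**Figure D4:**
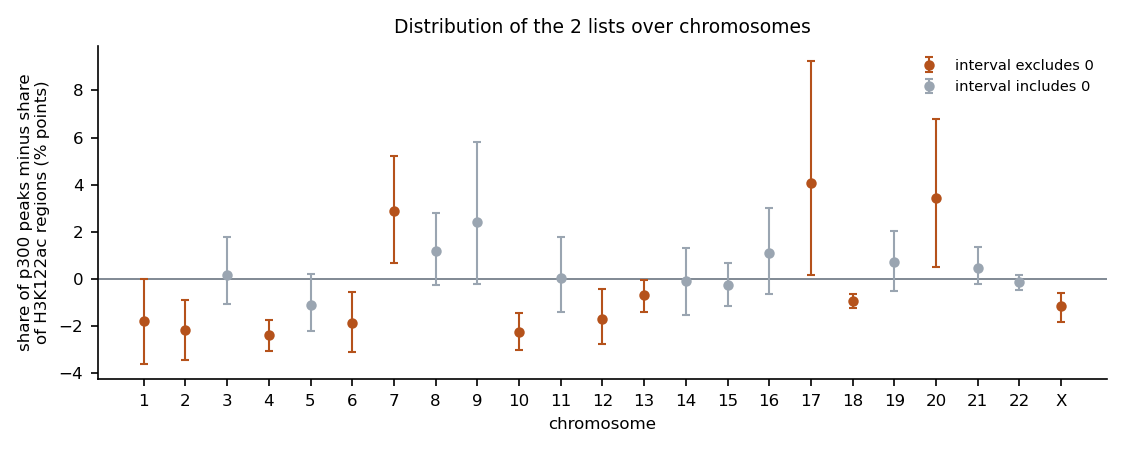
Share of all p300 peaks on each chromosome minus the share of all H3K122ac regions, in percentage points, with 95% intervals from 1000 bootstraps of 5 Mb blocks. The difference is 4.08 points on chromosome 17 and -2.39 points on chromosome 4, and the interval excludes 0 on 12 of 23 chromosomes.

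The frequency of overlap also differed between chromosomes. On chromosome 20, 113 of 165 p300 peaks overlapped H3K122ac (68.5%, Wilson interval 61.04 to 75.1%), and on chromosome 17 it was 121 of 193 (62.7%, interval 55.7 to 69.2%). On chromosome 19, 29 of 98 did (29.6%, interval 21.5 to 39.3%), although that chromosome held 10.6 H3K122ac regions per Mb. The lowest and highest shares were on chromosomes with few p300 peaks, chromosome 13 with 6 of 26 (23.1%, interval 11.03 to 42.1%) and chromosome 18 with 9 of 12 (75%, interval 46.8 to 91.1%). These chromosomes were picked after their values were seen. Without chromosome 17, which held most p300 peaks, the overlap over the other chromosomes was 50.6%, and without the 2 densest windows it was 50.3%.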

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

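Removing the 2 densest p300 windows, merging for the counts of intervals and chromosome shares, the position in the name and the nulls from rotated or width-weighted draws were chosen after the data were seen. Of 77 recomputed values, 71 kept their direction and their side of the threshold, or stayed within 1.5 times for a count. The share of p300 peaks that overlapped H3K122ac ran from 37.7% (highest-scoring 50% of both lists) to 54.7% (within 1 kb) and stayed above chance in every alternative run (permutation p = 0.0001). With at least 50% of the p300 peak inside it was 43.4%, and with overlapping intervals merged 50.8%. The share of clusters with p300 was 27.3% at a stitching distance of 5000 bp and 26.4% at 25000 bp. Against rotated peaks, the difference of 480 bp in H3K122ac width (permutation p = 0.0916), of 2.14 in H3K122ac score (p = 0.294, permutation) and of 0.807 in p300 score (p = 0.28, permutation) no longer passed 0.05. Each rotation met only 37.3 regions on average, against 1083 observed, so its range is wide by construction. Against 1083 regions drawn in proportion to width, the first 2 passed (permutation p = 0.0002), but these draws did not keep the crowding of p300 peaks. Chromosomes with differing shares fell from 12 to 7 in the highest-scoring 50% of both lists, and the cause was not tested. Promoter and gene-list alternatives were not run, since no hg18 annotation was used here. Depth is unknown in both lists, so a missing overlap means only that no interval passed the authors' threshold.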

Other observations

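The tests of the score threshold, of missed regions, of neighbourhoods and of width-weighted draws were chosen after the result they measure had been seen; the tests of the ends of the listed spans, merged intervals, window background and positions in the names were written down first. Within shared sites, the positions given in the names of p300 and H3K122ac intervals lay somewhat closer together than after exchange between sites. Over 1119 overlapping pairs, the median distance between the p300 position and the position of the highest-scoring overlapping H3K122ac region was 340 bp, with an interquartile range of 200 to 680 bp. When p300 offsets were exchanged between pairs within deciles of region width, the median was 435 bp, with a central 95% range of 415 to 460 bp (one-sided permutation test, p = 0.0001). Pairs were counted as listed, repeated p300 intervals included, and several can share 1 region. They are not independent, so this p may be too small. The positions were within 150 bp of each other in 192 pairs (17.2%), so most pairs were not superimposed. The p300 peaks outside H3K122ac regions also lay closer to such regions than shifted peaks did. Their median distance was 24.2 kb, with an interquartile range of 7.58 to 69.5 kb. The median gap between neighbouring H3K122ac regions was 52.6 kb. Outside peaks shifted by up to 1 Mb that missed every region lay at 43.5 kb (central 95% range 39.2 to 48.2 kb, one-sided permutation p = 0.0001).

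Overlap differed widely between 5 Mb windows. On chromosome 9 at 135000001-140000000, 36 p300 peaks made the third densest window, and 4 of them overlapped H3K122ac (11.1%, exact binomial interval 3.11 to 26.1%). Among the 14 windows with at least 20 p300 peaks, the share ran from this value to 90.9%, on chromosome 20 at 55000001-60000000. The chromosome 9 window held 24 H3K122ac regions, the lowest number among these 14 windows, the others of which held 37 to 209. Both windows were chosen after their values were seen, and no explanation was tested. The chromosome 9 window lies near the end of the span covered by the lists. So does the window with the next lowest share among the 14 (18.2%, chromosome 16 at 85000001-90000000). Windows at chromosome ends were not all low: on chromosome 16 at 1-5000000, 11 of 16 p300 peaks overlapped a region.

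The 1046 p300 peaks outside H3K122ac regions were the first pattern weighed. Weak peaks just past the calling threshold are not the whole cause, since 31.02% of the highest decile of p300 score also lay outside (Wilson interval 25.2 to 37.5%). Peaks within 1 Mb of the ends of the span covered by the lists, which can differ from the chromosome's own ends, could account for few of them. They were 58 of the 1046 (5.54%), although this was more often than for peaks inside regions (24 of 1119, 2.14%, Fisher's exact test, two-sided, p = 3.88e-05). No distance beyond 1 Mb was tried, so a broader excess near chromosome ends stays open. H3K122ac regions just under the authors' threshold stay open as a partial source, but their part was not measured. The lowest decile of H3K122ac score still met p300 20.8 times as often as rotated peaks did, the lowest ratio of all score deciles. In that decile 60 of 1769 regions met p300 (3.39%). Regions of every score decile exceeded rotated peaks, so this ratio cannot show that missed regions account for the outside peaks. The design gives no biological group to test against, and the difference between nuclease-digested and sonicated chromatin also stays untested.

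The second pattern was the crowding of p300 peaks in 2 of 588 windows of 5 Mb, chromosome 17 at 55000001-60000000 (65 peaks) and chromosome 20 at 45000001-50000000 (64 peaks), where the median window held 2. Several peaks counted in one interval do not explain it, because merging lowered the share of the list in these windows only from 5.96% to 5.00% and both stayed the densest. Extra copies of these segments in MCF-7 may raise the background there: each window held 17 peaks outside H3K122ac regions, above the upper end, 10, of the central 95% of all windows, but the windows were picked for their total number of peaks, and windows on chromosome 9 (135000001-140000000, 32 outside peaks), chromosome 16 (85000001-90000000, 18) and chromosome 11 (65000001-70000000, 17) held as many or more. Peaks inside H3K122ac regions were raised more, to 25.2 and 24.7 times the mean window against 9.56 times for outside peaks in both, but H3K122ac regions were raised too, to 2.63 and 6.95 times the mean, so this split does not argue against a raised background. Without the inputs, which were not analysed here, extra copies that make real sites easier to detect cannot be told apart from denser p300 binding.

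The third pattern was the greater width and score of H3K122ac regions that held p300. Chance hits on wide regions are unlikely to be the whole cause, since 480 bp lay above the 130 to 240 bp of draws of as many regions weighted by width and chromosome, and the score difference of 2.14 lay above their 0.382 to 1.24. The draws picked regions independently of each other, so their ranges may be too narrow for crowded p300 peaks. Both differences lay inside the ranges of rotated p300 peaks, -110 to 530 bp and -1.13 to 3.40. Rotation keeps the spacing of the peaks, but each rotation met only 37.3 regions on average, so these ranges are wide and exclude little. Within deciles of width the score difference was 0.513, so much of it goes with width. Copy gains that widen regions on chromosomes 17 and 20 stay open as a part of it, although the width difference was 440 bp without the 2 densest windows, and no biological explanation was tested.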
